A study of Homo sapiens with 7 samples.

How the data were processed

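MYCN binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kelly cells, an established human neuroblastoma line that carries many copies of the MYCN gene and an activating mutation of the receptor tyrosine kinase ALK. Per the labels, TAE684-sensitive cells received vehicle (DMSO) and TAE684-resistant cells received the ALK inhibitor TAE684 at 1 µM, each for 48 h. The labels describe 7 samples: 2 MYCN ChIP samples and 1 input sample of the sensitive cells, and 2 MYCN ChIP samples and 2 input samples of the resistant cells. Input is sheared chromatin sequenced without an antibody. It gives the background against which ChIP enrichment is judged.

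The files used were 2 peak lists, 1 named for each state. Per the labels, both ChIP samples of a state share 1 list, so no list of a single replicate was analysed here. How the 2 samples were combined is not given in the sources used here. The submitters' processing notes name STAR 2.5.1b, SAMtools 1.3.1, Picard, deepTools 2.2.4 and MACS2 2.1.1, and the build hg19, without saying what each was set to. STAR is a splice-aware aligner that can align genomic reads, and its settings, like the handling of duplicate reads, are not given in the sources used here. Each row of a list, as deposited, is 1 summit (the position of locally highest signal) inside an interval. The deposited fold enrichment is the ratio of the ChIP pileup to a local background at the summit. The deposited −log10 p-value and −log10 q-value belong to the same position. The deposited integer score is 10 times the −log10 q-value without its decimals. These are the authors' values for each peak and were used only to describe, rank or filter peaks within the list. Positions are given on hg19, counted from 1.

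The lists were first compared byte by byte, as fixed before the data were examined. They were identical, so only the list of the sensitive cells was described, and no comparison between sensitive and resistant cells was made. The gene table at hand is on another genome build. Gene names, promoter shares, the fixed gene lists, exon and intron shares and E-box counts were therefore not computed. The sites named are the 10 summits of highest fold enrichment, the rule fixed in advance for this case. The window on chromosome 2 up to 30 Mb was fixed in advance too. The regions defined by their background or their peak density were chosen after the values were seen, as were the widest intervals and the densest bins.

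The files give no read counts. The fold enrichment and the p-value of a summit were therefore solved together for the number of ChIP fragments over the summit and the local background. The relations were those MACS2 uses: the fold is the scaled ChIP pileup plus 1 over the background plus 1, and the p-value is the Poisson upper tail of the pileup rounded down. A single scale, 0.641, gave a whole number of ChIP fragments at 64657 of 64657 summits, with −log10 p matched within 0.0005. For 24 summits 2 numbers met this tolerance and the closer one was taken. Tested on simulated data with scales of 0.6, 0.73 and 0.88, the procedure returned the exact fragment number at 1958 of 1958, 1960 of 1968 and 1976 of 1976 summits. The background came out as the same lowest value, 1.61, at 4533 summits. At 38097 it was within 0.001 of a whole number, as for input fragments over the summit itself. At 18210 it was a multiple of 0.14 and at 3817 a multiple of 0.014 within 0.001, as for counts in 1-kb and 10-kb windows with a fragment length of 140 bp. Multiples of 0.14 are also multiples of 0.014, and some whole numbers are multiples of both, so the windows are not always told apart. Each summit was put in the first of these classes it met. Arbitrary values would lie on the finest step 14.3% of the time. The width of the narrowest interval is also 140 bp.

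Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules and neighbouring summits are not independent sites. No p-value was computed across samples. Densities use chromosome lengths up to the last peak, because no hg19 chromosome sizes were used here. These lengths, and the 1-Mb bins along them, also count unmappable sequence. Interval spacing was set against 100 uniform random placements, which also fall in unmappable sequence. Thresholds on q and fold, counting intervals in place of summits, and subsets of summits were tried as alternatives. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.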

Results

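The series was designed to compare genome-wide MYCN occupancy between Kelly neuroblastoma cells that respond to the ALK inhibitor TAE684 and Kelly cells that resist it. MYCN is a basic helix-loop-helix transcription factor that binds DNA as a partner of MAX. The labels place 2 ChIP samples in each state, with 1 input sample for the sensitive cells and 2 for the resistant cells. Peaks came as 1 list per state, so no value below has a replicate error.

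The lists of the sensitive and the resistant cells held the same peaks. All 64657 rows were identical at the same line, and both files had 7053300 bytes. In the list of the resistant cells, 64657 peak names carried the name of the sensitive list and 0 carried the name of the resistant list. The question of how MYCN occupancy differs between the states was therefore not answered from these files, and every value below refers to the sensitive, vehicle-treated cells. MYCN peaks of resistant cells were not analysed here.

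Many MYCN peaks were called in sensitive Kelly cells, and most of the intervals were short. The list held 64657 summits in 47765 separate intervals, which together covered 19.6 Mb. The median interval was 279 bp wide, with quartiles of 191 and 517 bp. A single summit was found in 76.4% of the intervals (95% CI 76.0 to 76.8). Intervals with 2 summits made up 15.8%, those with 3 summits 5.18%, and those with 4 or more 2.63%. The median of the highest fold enrichment rose with the number of summits, from 5.40 in intervals with 1 summit to 6.98 with 2, 7.90 with 3 and 8.78 with 4 or more. These medians compare highest values, which grow with the number of summits they are taken from. The widest interval lay on chromosome 2 from 43451285 to 43455032. It spanned 3748 bp, held 9 summits and reached a fold enrichment of 8.04. An interval on chromosome 17 from 42295693 to 42298946 held 10 summits, the most in any interval, and reached 12.6. A further interval with 10 summits, on chromosome 2 from 5831176 to 5834119, reached 10.2, and one on chromosome 3 from 128206602 to 128209306 reached 4.17.

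By fold enrichment, most sites were moderately enriched over input and a small group was strongly enriched. The authors' fold enrichment had a median of 5.35 and quartiles of 3.90 and 7.54. It was at least 10 at 7731 summits, which is 12% of the list (95% CI 11.7 to 12.2). It was at least 20 at 503 summits (0.778%, 95% CI 0.712 to 0.849) and at least 30 at 76 summits (0.118%, 95% CI 0.0926 to 0.147). These shares depend on the local background. A fold enrichment of at least 20 was found at 0% of the 17704 summits with a background of 8 to 12 input fragments. This share was almost fixed in advance, since the list's highest ChIP fragment number would reach 20 only at backgrounds barely above 8. A fold enrichment of at least 20 was also found at 0% of the 10143 with a higher background, where even that number would give less. The lowest −log10 q was 2.01 and the median 14.4.

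The strongest site lay on chromosome 1 from 99744847 to 99745481, with its summit at 99745212, a fold enrichment of 57.2 and a −log10 q of 250.5. The next was on chromosome X from 106919871 to 106920490, with a fold enrichment of 50.8. A site on chromosome 9 from 17065086 to 17065403 reached 48.1. One on chromosome 10 from 99419297 to 99419763 reached 45.1 and had the second highest −log10 q of these 10 sites, 210.9. Sites on chromosome 7 from 22186699 to 22187071 and on chromosome 3 from 141998595 to 141999174 had fold enrichments of 44.9 and 44.4. On chromosome 12, a site from 65694554 to 65694880 reached 42.0 and a site from 20365634 to 20366119 reached 40.7. The remaining sites of the 10 were on chromosome 2 from 46566381 to 46566740, with a fold enrichment of 41.5, and on chromosome 8 from 66057244 to 66057995, with 40.5. Of these 10 sites, 8 were intervals with a single summit, as were 76.4% of all intervals. At 5 of the 10 sites the input was no higher than its genome-wide mean. A ranking by fold enrichment favours such sites, since the background divides the fold.

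The depth behind these values was recovered from the fold enrichment and p-value of each summit. ChIP fragments were 1.56 times as many as input fragments, at a genome-wide mean of 17.9 ChIP and 11.5 input fragments per kb. A summit was covered by a median of 63 ChIP fragments, with quartiles of 41 and 102 and a lowest value of 13. The highest value was 280, reached at 7 summits, and it equals 2 times the fragment length of 140 bp. At least 252 fragments, or 90% of that value, were found at 410 summits (0.634%, 95% CI 0.574 to 0.698). At the 10 strongest sites the number ran from 163 on chromosome 8 to 266 on chromosome 1.

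**Figure D1:**
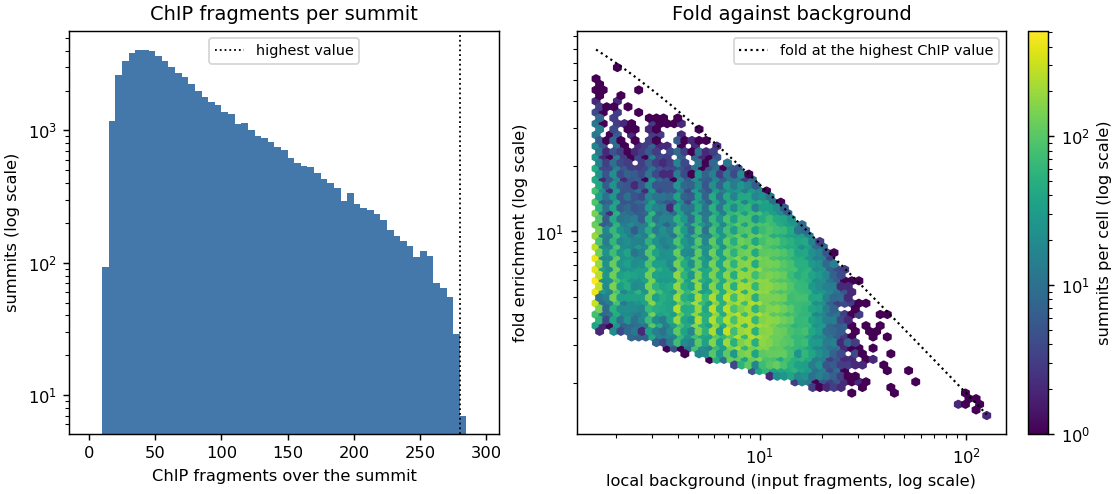
Left, number of summits (log scale) by ChIP fragments over the summit, in steps of 5, with the highest value of 280 as a dotted line. Right, fold enrichment against local background for all 64657 summits (both axes log, colour gives summits per cell). The dotted line is the fold that 280 ChIP fragments would give. Because 280 is the list's highest number, no summit can lie above it.

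The input was not flat at MYCN sites. The local background had a median of 7.56 input fragments, 4.70 times the genome-wide mean of 1.61. It equalled the genome-wide mean at 4533 summits, or 7.01% of the list (95% CI 6.82 to 7.21). Since the peak caller takes the largest of several windows, part of this ratio arises with a flat input: the same rule applied to a simulated flat input gave 1.24.

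MYCN summits were unevenly spread over the chromosomes. Over chromosomes 1 to 22 and X there were 21.3 summits per Mb up to the last peak. These lengths count unmappable sequence, whose share may differ between chromosomes, so the order by density could change without it. Copy number, which raises ChIP and input signal alike, was not accounted for in these densities. Chromosome 19 had the highest density, 56.0 summits per Mb, followed by chromosome 17 with 47.6 and chromosome 22 with 35.3. Chromosome X had 9.48, chromosome 13 had 11.8 and chromosome 4 had 12. Chromosome 1 held the largest number, 7021 summits. The median fold enrichment ran the other way at these extremes, with 4.92 on chromosome 19, 4.87 on chromosome 17 and 4.60 on chromosome 22, against 5.98 on chromosome X and 6.0 on chromosome 4. The median local background also differed, with 11.6 input fragments on chromosome 22 and 10.4 on chromosome 17 against 4 on chromosomes 18 and X. Fold enrichment is measured against that background.

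**Figure D2:**
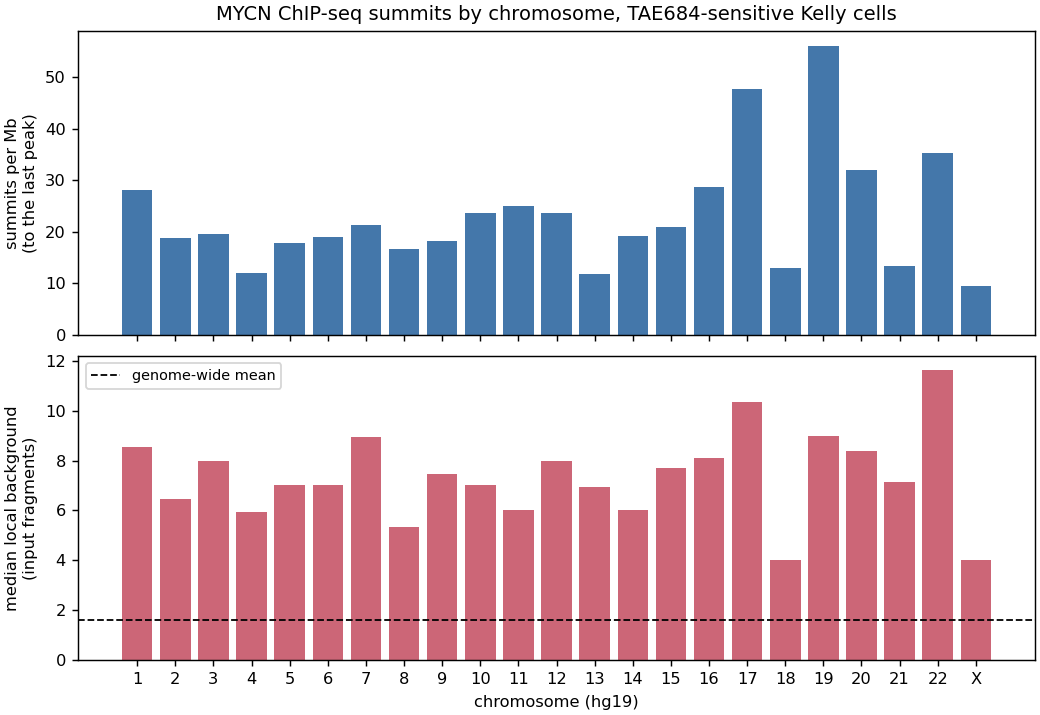
Summits per Mb up to the last peak (top) and median local background in input fragments (bottom) for each chromosome of sensitive Kelly cells, with the genome-wide background of 1.61 as a dashed line. Chromosomes 19 and 17 have the highest densities, 56.0 and 47.6 per Mb, and chromosomes 18 and X the lowest median background, 4.

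Within chromosomes the sites were clustered. Another interval lay within 10 kb for 58.8% of the intervals (95% CI 58.4 to 59.3), against a mean of 30% and a highest value of 30.6% in 100 random placements. Of 3049 bins of 1 Mb, 317 held no summit, while the densest 305 bins held 34.7% of the summits. Both the bins and the random placements include unmappable sequence, where no peak can be called, which can add to the apparent clustering. Parts of 1 enriched stretch that were called as separate intervals would add to it too. On chromosome 1, for example, an interval ending at 149224267 was followed by one starting at 149224360. How many neighbours are of this kind was not tested, and copy number was not accounted for in the bins. The densest bin was on chromosome 17 from 79 to 80 Mb, with 186 summits and a median fold enrichment of 4.60. It was followed by chromosome 19 from 1 to 2 Mb with 169 summits, chromosome 16 from 85 to 86 Mb with 147, and chromosomes 1 from 156 to 157 Mb and 9 from 139 to 140 Mb with 138 each. Among occupied bins ranked by their number of summits, the median fold enrichment was 5.90 in the lowest 25% and 5.06 in the highest 25%. The median background in these bins was 4 and 8.68 input fragments.

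The start of chromosome 2, which holds the amplified MYCN gene of this cell line, was examined separately because copy number raises ChIP and input signal alike. Its first 30 Mb held 964 summits, or 32.1 per Mb. That is 1.51 times the density over chromosomes 1 to 22 and X (95% CI 1.41 to 1.61). Densities in 30-Mb windows ranged from 3.33 to 53.8 per Mb with a median of 16.9, and 78 of 89 other windows had a lower density.

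A short region inside this window stood apart from the rest of the list. From 16449646 to 16772949 on chromosome 2, a span of 323 kb, all 10 summits had a fold enrichment between 1.41 and 1.76. These were the 10 lowest values of the list, with no other summit under 1.8. The local background there was 93.9 to 126 input fragments, which is 58.4 to 78.1 times the genome-wide mean. Its highest value elsewhere was 56.0. The 10 summits held 234 to 280 ChIP fragments, with a median of 270. With the background measured there, the list's highest number of 280 would give a fold enrichment of 1.43 to 1.90. In the 1 Mb on each side, 43 summits had a median fold enrichment of 6.07, a median background of 3.50 and a median of 48 ChIP fragments. The stretch just before this region, from 15815795 to 16449645, held no peak over 634 kb, and by its textbook map position the MYCN gene lies in it. That stretch is part of the 1 Mb on this side, so the median background of 3.50 does not describe it. Stretches at least as long numbered 562, or 1.18% of the 47740 gaps between neighbouring intervals, whose median was 17.6 kb. This share counts gaps, not base pairs, so a larger share of positions lies in such stretches.

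**Figure D3:**
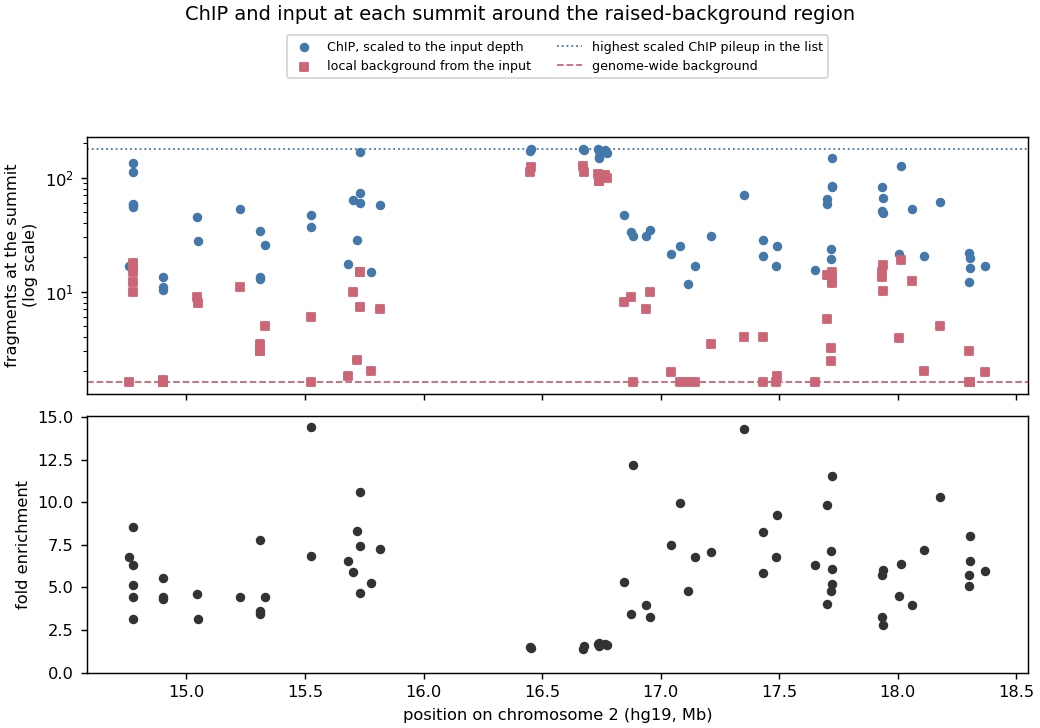
Scaled ChIP pileup and local background at each summit on a log scale (top) and fold enrichment (bottom) against position on chromosome 2 in Mb, hg19. The 10 summits between 16449646 and 16772949 lie close to the highest scaled ChIP pileup of the list (dotted line) with a background of 93.9 to 126, and their fold enrichment is 1.41 to 1.76.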

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

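The tests of the low fold enrichment on chromosome 2 were chosen after the values were seen.

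The input, which was used as background and not compared itself, had a strong local signal. The local background of the region on chromosome 2 from 16449646 to 16772949 reached 126 input fragments, against a genome-wide mean of 1.61.

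The low fold enrichment in this region may come from the way reads were counted. The highest number of ChIP fragments at any summit, 280, is what 1 fragment per position and strand allows for a length of 140 bp, which suggests that duplicate reads were removed. All 10 summits of the region held at least 83.6% of that number, but this does not decide the point, since 74.3% to 95% of it was already needed to pass the lowest p-value of the list at their backgrounds. Such a limit would allow no fold above 1.90 there, so it and weaker MYCN binding per gene copy cannot be told apart. Whether the input was limited in this way too is not known. Its background there equals 33.5% to 44.8% of the fragment positions in 10 kb. With such a limit its ratio to the genome-wide mean would be too low. The neighbouring 634 kb without a peak could follow from the same limit if the input there exceeded 133 fragments, the background at which a full ChIP pileup no longer passes the lowest p-value of the list, but no background value exists without a summit.

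Outside this region, 20 summits had a background at least 20 times the genome-wide mean, 11 of them on chromosome 1, and at 20 of 20 it was within 0.001 of a whole number of input fragments.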

How the results depend on the processing

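No paired analysis was possible because each state has 1 list for both ChIP samples, and for the same reason no replicate could be left out. The number of summits, 64657, fell to 41502 with a −log10 q of at least 10 and to 36069 with a fold enrichment of at least 5. It stayed within 1.5 times with a −log10 q of at least 5 (56628) and with 1 count per interval (47765). The density ratio of the first 30 Mb of chromosome 2 was 1.49 to 1.56 under the q and fold thresholds and per interval, and 1.36 when only 1-Mb bins with at least 1 summit were counted. The ratio of the median background to the genome-wide mean, 4.70, was 4.98 for summits with a −log10 q of at least 10, 4.36 for the strongest summit of each interval, 3.73 for intervals with 1 summit and 4.62 without the first 30 Mb of chromosome 2. The bin count, the per-interval density and all background alternatives were chosen after seeing the data. Alternatives fixed before the data were examined for the overlap of the lists, equal list sizes, promoters, gene lists and E-boxes were not run, because the lists were identical and no hg19 annotation or sequence was used. No summit with fewer than 13 ChIP fragments was listed. How far depth or the threshold of the list sets this number was not tested.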

Other observations

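The test of the identical lists was chosen after the result was seen, and the tests of the input background before.

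Summits were also described by their local background. Fold enrichment and the number of ChIP fragments are not independent of it, since the background divides the fold and sets how many fragments a summit needs to be listed. The 4533 summits at the genome-wide background had a median fold enrichment of 6.78 with a median of 26 ChIP fragments. Their intervals had a median width of 198 bp, and 88.2% were the only summit of their interval. The 10143 summits with a background above 12 input fragments had a median fold enrichment of 4.51 with a median of 114 ChIP fragments. Their intervals had a median width of 697 bp, and 40.0% were alone. A fold enrichment of at least 20 was found at 3.11% of the former (95% CI 2.62 to 3.66) and at 0 of the latter, where even the highest number seen, 280 ChIP fragments, would give less.

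Which sites rank highest depends on the measure, and the background of each ranking follows in part from its definition. The 1000 summits of highest fold enrichment and the 1000 with most ChIP fragments shared 90 summits, against 15.5 for independent lists of that size. The lists are not independent, since the fragment number is part of the fold, so some sharing above 15.5 is built in. In what follows, the former are the summits of highest fold enrichment and the latter those with most ChIP fragments. The former had a median background of 3 and a median width of 483 bp, and 66.1% were alone in their interval. The latter had a median background of 13.0 and a median width of 886.5 bp, and 41.1% were alone.

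The raised input at MYCN summits, 4.70 times its genome-wide mean, was weighed against technical explanations. Taking the largest of several windows gave a ratio of only 1.24 with a flat simulated input, so this is not the whole cause. Copy-number gain as the whole cause goes against the tables too, since 37.5% of the summits at or above the median background shared a 1-Mb bin with a summit at the genome-wide mean. Such summits lay in 71.9% of the bins, which decides nothing, because the median bin held 14 summits and 50% of all summits reach the median by definition. Gains much shorter than 1 Mb stay open, and no biological explanation was tested.

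A separate peak calling on the resistant libraries is not what the list of the resistant cells holds, since 64657 of its 64657 peak names carry the name of the sensitive list. Both lists hold the same rows, and their identity says nothing about MYCN binding in resistant cells.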
